A study of Mus musculus with 6 samples.

How the data were processed

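Olfactory epithelium of keratin 5 lineage-traced mice was separated from respiratory tissue and dissociated, and TdTomato-positive cells were sorted. PolyA RNA was made into Nextera XT libraries and sequenced on an Illumina HiSeq, per the labels. There were 3 libraries from uninjured mice and 3 from mice taken 18 h after an 8 h exposure to methyl bromide gas at 180 ppm. Each library pooled cells of several animals, per the labels, so a library is the replicate.

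The authors deposited 1 table with a value per gene and library. FastQC, TopHat, Cuffdiff and the mouse genome build mm9 are named in the submitters' processing notes, whose versions, roles and order were not given in the sources used here. The deposited values are taken here to be FPKM, because Cuffdiff is named and the gene column has the heading Cuffdiff writes, but the table itself does not name the unit. Any scaling between libraries by the authors, the gene annotation, the filter behind the 8078 listed genes and the handling of reads with several matches were not given in the sources used here. In 131 entries several gene symbols are joined. Such an entry is not read as the level of any single member, but in the gene lists it stood for the listed symbols it joins. The lowest value, 0.001, stands in 549 genes in at least 1 library. Nothing in the sources used here says what that value stands for. Read depth is unknown, and no steps of whole reads were found in the values: at most 2.89% of the ratios of low genes between libraries agreed within 1%. No intervals from counting were therefore computed. Summed FPKM ranged from 164265 to 231755. The entry of Mir703 alone took 22.0% to 25.4% of that sum in uninjured libraries and 8.01%, 11.6% and 18.6% in injured replicates 1 to 3. No 2 libraries held identical values.

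The choice of test depended on the unit of the table, and for FPKM it was limma. The comparison was injured against uninjured with 3 libraries each and no covariate. Genes with a mean of at least 1 FPKM, 7987 of them, were tested with limma (version 3.58.1 in R 4.3.3) on log2(FPKM + 1), with eBayes using trend and robust variances and Benjamini-Hochberg adjustment at 0.05. The test was tried on simulated data for this comparison with 200 of 7987 genes changed: it recovered 11.9% of changes of 1, 56.7% of changes of 2 and 81.8% of changes of 3 on the log2 scale, with 8 false calls. In it genes were drawn independently, each with the same SD in all 6 libraries. In the real data the median SD was 0.253 in uninjured and 0.459 in injured libraries. These rates may therefore not hold for the real libraries.

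Before the data were examined, 44 gene lists of pathways and of cell types that the sort could hold were fixed, with 807 symbols. Of these, 528 had an entry in the table, 23 of them a joined one and 1 an older symbol. The 39 lists with at least 3 genes tested were compared with all other genes by limma's camera with a preset correlation of 0.01 and with an estimated correlation, and tested by fry for a movement of their own. fry adjusted p values were under 0.05 for 0 lists in a single direction and for 2 lists in either direction, the Wnt list (0.00427) and the sustentacular cell list (0.00817). In simulated data a list of 25 genes raised by 0.5 was called by camera with the preset correlation (adjusted p = 4.75e-09) and 0 of 38 others were. The simulated genes varied independently, whereas that list, ribosome biogenesis, had an estimated correlation of 0.572 in the real data. The simulation therefore cannot show how often camera calls a correlated list falsely. Counts per list were adjusted over all genes tested and over the list alone. Genes were named by a rule fixed beforehand: 12 genes of the cell type and its known regulators, up to 12 genes with the largest increases and 12 with the largest decreases past the threshold whose libraries do not overlap, and up to 4 members per list past the threshold or else the 2 most abundant. A few others, chosen after their values were seen, illustrate a group or a library. A gene that the rule names is not reported here.

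Alternatives fixed beforehand were a replicate block, leaving out each library, no filter or a mean of at least 5 FPKM, upper-quartile and quantile scaling, limma without trend and robust steps, pseudocounts of 0.1 and 0.5, a threshold of 0.01 and a 2-fold minimum. Library quality weights, leaving out genes with a value of 0.001 and leaving out Mir703 with rescaling were added after the data were seen. Gene positions were left out, since the build of the files was not used here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.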

Results

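Horizontal basal cells are the reserve stem cells at the base of the olfactory epithelium, and they become active when the tissue above them is destroyed. RNA was sequenced from such cells of 12-week-old mice in which a tamoxifen-inducible Cre recombinase under the keratin 5 promoter had switched on the red fluorescent protein TdTomato 2 weeks earlier, and cells were sorted on that fluorescence. The 3 uninjured libraries came from undisturbed epithelium. The 3 injured libraries came from epithelium taken 18 h after an 8 h exposure to methyl bromide, a gas that strips away most of the olfactory epithelium. Each library was made from cells pooled over several animals. The table gave a value per gene for each library, taken here to be FPKM. Read depth was unknown. Summed FPKM lay between 164265 and 231755 per library, and 1.94% to 3.16% of genes stood at the table's lowest value of 0.001. Group values below are means ± SD over n = 3 libraries in FPKM unless single libraries are named, and changes are injured minus uninjured on the log2(FPKM + 1) scale, which understates the change of low genes.

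The comparison asks how expression in the sorted cells differs 18 h after the lesion. The uninjured libraries also held genes from the lists of other cell types, with Plunc at 4082 ± 988, Stoml3 at 416 ± 129 and Dcn at 141 ± 23.5 FPKM. Whether a lower list reflects fewer such cells or lower expression was not tested. At 18 h after the lesion Xist, the RNA that silences an X chromosome, was at 0.324 ± 0.249 FPKM against 29.4 ± 3.82 without injury. It was the only gene past the threshold. Genes of the Y chromosome (Ddx3y, Eif2s3y, Kdm5d and Uty) stood higher in the injured libraries, with a median log2 change of 1.76, though none passed. A difference in sex between the pools fits both, except in uninjured replicate 1, which had raised Y-linked genes but Xist at 27.4 FPKM. The sex of the animals was not given. Injury and sex can therefore not be told apart in the comparisons below. As groups, genes of DNA replication stood higher in the injured libraries, with 19 of 20 members showing a positive change and a median log2 change of 1.07, and so did genes of the wound keratinocyte and of ribosome biogenesis. These calls were lost at adjusted p = 0.643, adjusted p = 0.816 and adjusted p = 0.902 with an estimated correlation, and no member passed over all genes tested. Genes of the mature olfactory neuron stood lower, with all 11 members showing a negative change and a median of -1.30 (adjusted p = 0.643 with an estimated correlation), again with no member past the threshold over all genes. The horizontal basal cell transcription factor Trp63 was at 179 ± 19.9 FPKM in uninjured cells and at 117 ± 20.9 after injury. Injured replicate 2 shared the low Xist level but lay nearer to the uninjured libraries for Timp1, an inhibitor of matrix metalloproteinases, which was at 138, 9.72 and 224 FPKM in injured replicates 1, 2 and 3 against 2.13 ± 0.629 without injury.

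With limma on 7987 genes, no gene was higher and 1 was lower at an adjusted p of 0.05, and limma without its trend and robust steps called 3 higher and 3 lower. At an unadjusted p of 0.05 there were 571 higher and 323 lower genes, 894 in all, where 399 would be expected by chance. The injured libraries did not overlap the uninjured ones for 958 genes that were higher and 539 that were lower, which is 18.7% of the genes tested against 10% by chance. The median log2 change of all genes was 0.155, and it was -0.01 after upper-quartile scaling and 0.01 after quantile normalization, so the list medians below are to be read against that shift. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.888 to 0.907 between uninjured libraries, 0.853 between injured replicates 1 and 3, and as low as 0.737 between injured replicate 2 and another injured library. Without injured replicate 2, which leaves 2 injured libraries, 278 genes were higher and 92 lower. Among the lists below whose members did not pass over the 6 libraries, 6 NRF2 genes, 4 heat shock genes and 3 genes each of the urokinase, hemidesmosome and glycolysis lists were higher without that library, as were 2 each of the chromatin and NF-kB lists, with 1 NF-kB gene, Ccl20, lower. By camera 3 lists were higher and 6 lower, 0 and 0 with an estimated correlation, and other groupings of the same 6 libraries called up to 22 lists.

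**Figure D1:**
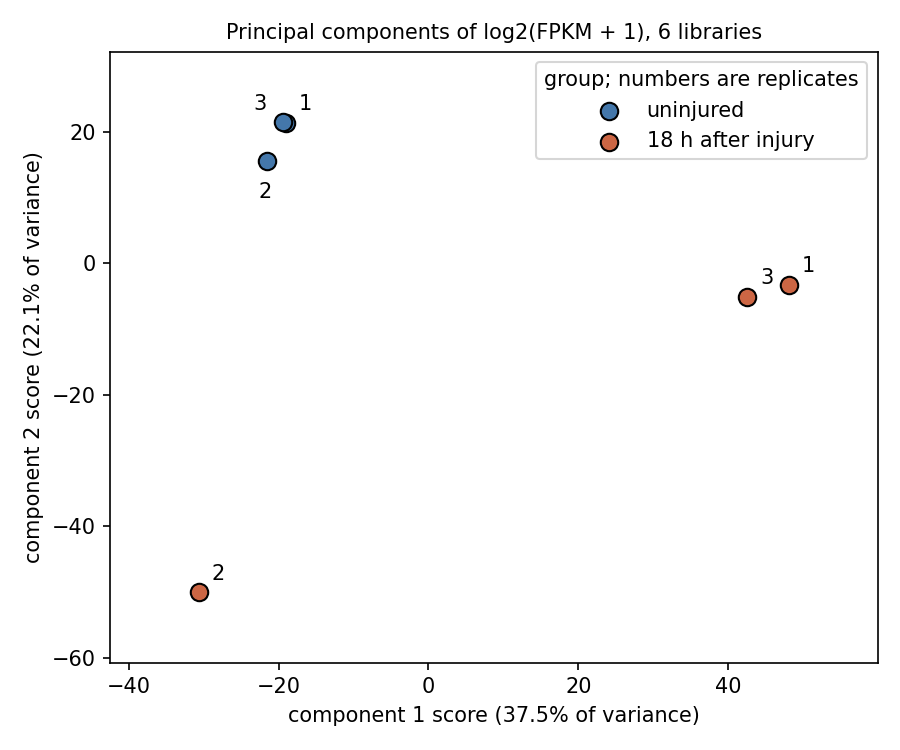
Scores of the 6 libraries on the first 2 principal components of log2(FPKM + 1), with the group as colour and the replicate number beside each point. Component 1 holds 37.5% of the variance and sets injured replicates 1 and 3, at 48.1 and 42.6, apart from injured replicate 2 at -30.6 and from the uninjured libraries at -21.6 to -19.0. Component 2 holds 22.1% and has injured replicate 2 at -50.02, injured replicates 1 and 3 at -3.25 and -5.10, and the uninjured libraries at 15.55 to 21.46.

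Genes that mark horizontal basal cells and hold them to the basement membrane showed no shift in common that passed. Of 11 genes tested on the basal cell identity list none rose or fell, and the list median was -0.12 (camera adjusted p = 0.239), which became 0.09 without injured replicate 2, with 1 member higher. Icam1, a surface adhesion molecule of these cells, was at 15.1 ± 1.22 FPKM in uninjured libraries and at 27.3, 8.21 and 30.3 in injured replicates 1 to 3. The epidermal growth factor receptor Egfr was at 24.7 ± 2.62 before and 27.7 ± 17.5 after injury. Krt14 shares a single table entry with Krt13, Krt15, Krt16, Krt17, Krt19 and Krt42, and that entry was at 522 ± 14.8 FPKM in uninjured cells and at 917, 355 and 853 in the injured libraries, so Krt14 alone cannot be read. Perp, a desmosome-associated p53 target, was at 392 ± 413 without injury, with 869 of it in uninjured replicate 2, and at 199 ± 76.4 with it. Krt5 and Sox2 were not analysed here. None of the 12 hemidesmosome and basement membrane genes passed (median 0.04, adjusted p = 0.755, and a median of 0.37 without injured replicate 2), with Dst at 95.2 ± 33.5 and 66.4 ± 24.8 and Itgb1 at 59.7 ± 9.93 and 66.6 ± 33.6 FPKM. None of the 11 junction genes passed either (median 0.27, adjusted p = 0.755), with the desmosomal linker Dsp at 71.2 ± 7.60 and 63.4 ± 14.8 and E-cadherin (Cdh1) at 54.8 ± 2.38 and 85.6 ± 45.8.

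Genes of Notch and Wnt signalling stood lower in the injured libraries. The Notch list had a median of -0.41 over 10 genes (camera adjusted p = 0.00786, and adjusted p = 0.660 with an estimated correlation), and no member passed on its own. Without injured replicate 1 the median was -0.24 (adjusted p = 0.0579). Its transcriptional targets Hes1 and Hey1 were at 87.0 ± 12.3 and 108 ± 13.3 FPKM in uninjured cells and at 55.1 ± 7.86 and 69.4 ± 6.92 after injury, below every uninjured library in each of the 3 injured ones. Hes1 and Notch2 are also on the sustentacular cell list, which stood lower too (camera adjusted p = 0.00125, and adjusted p = 0.469 with an estimated correlation). Whether the Notch list moved apart from those cells was not tested. The receptor Notch1 was at 11.6 ± 0.797 without injury and at 5.85, 4.69 and 12.5 in injured replicates 1 to 3, and its ligand Jag1 was at 7.03 ± 1.07 and at 3.98, 4.25 and 8.25. The Wnt list had a median of -0.27 over 15 genes (adjusted p = 0.00276, and adjusted p = 0.814 with an estimated correlation). It was -0.17 without injured replicate 2 (adjusted p = 0.0473, and adjusted p = 0.381 with an estimated correlation). Within it 0 genes fell over all genes tested and 1 fell adjusted over the list alone, Lgr6, a receptor for R-spondins, from 10.3 ± 0.386 to 4.63 ± 0.626 FPKM. The secreted Wnt antagonist Sfrp1 was at 108 ± 2.17 and 60.2 ± 12.0, and Ctnnb1, which encodes beta-catenin, at 120 ± 6.63 and 128 ± 30.3. Neither the 11 genes of the EGF family (median 0.10, adjusted p = 0.539, and a median of 0.65 without injured replicate 2) nor the 15 of the TGF-beta and BMP pathway (median -0.16, adjusted p = 0.119) held a gene that passed. Among them Errfi1, a feedback inhibitor of the EGF receptor, was at 41.7 ± 19.8 and 78.3 ± 70.5 and Spry2 at 34.8 ± 1.70 and 28.9 ± 11.8. The BMP targets Id1 and Id2 were at 56.6 ± 5.30 and 28.1 ± 6.11 and at 32.2 ± 3.97 and 27.6 ± 7.72 FPKM.

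DNA replication genes rose as a list. The replication and G1/S list had a median of 1.07 over 20 genes (camera adjusted p = 4.94e-08, and adjusted p = 0.643 with an estimated correlation). Over all genes tested 0 members rose, 7 did without injured replicate 2, and 11 rose adjusted over the list alone. The replicative helicase subunits Mcm2 and Mcm3 went from 2.25 ± 0.778 and 1.62 ± 0.0565 to 12.2 ± 6.26 and 11.04 ± 5.88 FPKM. The GINS subunit Gins2 went from 4.99 ± 1.36 to 22.3 ± 10.7 and the primase subunit Prim1 from 4.87 ± 0.310 to 12.1 ± 2.79. Each of these 4 genes was higher in 3 of 3 injured libraries than in any uninjured one. Of the 2 most abundant members, Mcm4 was at 10.2 ± 4.99 and 21.7 ± 10.9, and Slbp, the histone mRNA binding protein, at 11.5 ± 0.767 and 16.4 ± 4.86. None of the 15 mitotic genes passed (median 0.36, adjusted p = 0.463), and the list mean was -0.03, 1.05 and 0.03 in injured replicates 1 to 3, with a median of -0.08 without injured replicate 2. The proliferation marker Mki67 was at 3.71 ± 0.164 FPKM in uninjured cells and at 3.34, 9.45 and 3.82 in injured replicates 1 to 3. Top2a was at 4.58 ± 0.339 and at 6.45, 14.8 and 7.24, and Ube2c at 5.10 ± 0.789 and at 5.55, 13.1 and 4.01. Of 11 cyclin D and CDK inhibitor genes none passed (median 0.30, adjusted p = 0.755), with Ccnd1 at 30.9 ± 7.45 and at 79.1, 33.5 and 102 FPKM, and its partner kinase Cdk4 at 41.0 ± 8.61 and 74.5 ± 20.2.

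Ribosome biogenesis genes were higher as a list, with all 25 members showing a positive change and a median of 0.65 (camera adjusted p = 4.63e-05, and adjusted p = 0.902 with an estimated correlation), although no member passed. The list mean was 0.96, 0.00 and 1.17 above that of uninjured libraries in injured replicates 1 to 3, and 8 members passed without injured replicate 2. The growth regulator Myc was at 11.6 ± 2.87 FPKM without injury and at 25.6, 8.49 and 29.8 in injured replicates 1 to 3. The nucleolar proteins Ncl and Npm1 were at 56.2 ± 31.8 and 97.4 ± 84.9 and at 47.7 ± 9.41 and 65.9 ± 24.1. The 23 cytosolic ribosomal protein genes showed no such shift (median -0.17, adjusted p = 0.0555), with Rplp1 at 553 ± 166 and 579 ± 464 and Rps9 at 480 ± 97.3 and 695 ± 301. The 19 chromatin regulators had a median of 0.40 (adjusted p = 0.0927). Over all genes tested 0 rose and 1 rose adjusted over the list alone, the architectural protein Hmga2, from 2.83 ± 0.699 to 25.6 ± 18.8 FPKM. The entry of its relative Hmga1, joined with a retrogene copy, was at 38.6 ± 12.5 and 134 ± 76.9.

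Wound keratinocyte genes rose as a list, with a median of 1.08 over 11 genes (camera adjusted p = 0.00403, and adjusted p = 0.816 with an estimated correlation). Over all genes tested 0 members rose (5 without injured replicate 2), and 2 rose adjusted over the list alone. These were Sprr1a, a precursor of the cornified envelope, from 6.03 ± 1.13 to 47.8 ± 22.7 FPKM (log2 change 2.67, limma adjusted p = 0.0927), and Krtdap, a keratinocyte differentiation factor. Krtdap stood at the table's lowest value in uninjured replicates 1 and 3 and at 0.619 in replicate 2, and at 13, 3.33 and 17.9 in the injured libraries. The call of the list was lost without injured replicate 1 (median 0.53, adjusted p = 0.119). S100a11 was at 125 ± 51.0 and 294 ± 213. None of the 16 genes of the urokinase and matrix remodelling list passed (median 0.59, adjusted p = 0.0871), and without injured replicate 2 the list had a median of 0.89 (adjusted p = 0.00305, and adjusted p = 0.471 with an estimated correlation). Besides Timp1 it held Serpine2, at 49.8 ± 13.03 and 40.7 ± 7.69, and the urokinase receptor Plaur, at 3.17 ± 0.925 and at 33.0, 4.13 and 52.2 in injured replicates 1 to 3. The NF-kB and cytokine list had a median of 0.61 over 22 genes (adjusted p = 0.119), and without injured replicate 2 a median of 1.11 (adjusted p = 0.000263, and adjusted p = 0.365 with an estimated correlation). Over all genes tested 0 of its members fell and 1 fell adjusted over the list alone, the chemokine Ccl20, from 36.3 ± 18.0 to 7.41 ± 2.81 FPKM. Nfkbiz was at 20.9 ± 4.91 and 33.2 ± 22.6 and the receptor Tnfrsf1a at 24.3 ± 2.88 and 30.3 ± 12.0.

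No member of the immediate early (16 genes, median 0.27, adjusted p = 0.924), interferon (13 genes, median -0.18, adjusted p = 0.263) or STAT3 and gp130 lists (12 genes, median -0.08, adjusted p = 0.239) passed. Their medians without injured replicate 2 were 0.82, 0.27 and 0.21, none past the threshold as a list. Fos was at 328 ± 119 FPKM in uninjured libraries and at 259, 104 and 473 in injured replicates 1 to 3, and the phosphatase Dusp1 at 210 ± 46.1 and at 268, 107 and 667. The joined entry of Ifitm2 and Ifitm3 was at 896 ± 253 and 1865 ± 938 and B2m at 333 ± 45.5 and 288 ± 117. Stat3 was at 40.8 ± 11.4 and 52.5 ± 48.0, and the shared cytokine receptor subunit Il6st at 103 ± 15.5 and 74.3 ± 26.4.

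Stress and energy metabolism lists did not pass over the 6 libraries, and 3 of them passed without injured replicate 2. The medians were 0.36 for 25 genes of the NRF2 and glutathione list (camera adjusted p = 0.265), 0.33 for 21 unfolded protein and integrated stress genes (0.309), and 0.52 for 13 heat shock genes (0.119). Without injured replicate 2 the NRF2 list had a median of 0.60 (adjusted p = 0.00553, and adjusted p = 0.340 with an estimated correlation) and the heat shock list a median of 0.96 (adjusted p = 0.00307, and adjusted p = 0.463 with an estimated correlation). Over the 6 libraries the medians were -0.01 for 17 p53 targets (0.643), 0.48 for 22 glycolysis and hypoxia genes (0.341), 0.08 for 23 genes of cholesterol and fatty acid synthesis (0.274) and 0.16 for 26 genes of oxidative phosphorylation (0.982). The glycolysis list, without injured replicate 2, had a median of 0.71 (adjusted p = 0.0131, and adjusted p = 0.579 with an estimated correlation). The ferritin heavy chain Fth1 was at 1234 ± 227 and 1435 ± 558 FPKM. Among chaperones, Hspa5 was at 168 ± 28.0 and 248 ± 102, Hsp90b1 at 194 ± 18.5 and 277 ± 61.2 and Hsp90ab1 at 420 ± 46.8 and 618 ± 175. Btg2 was at 77.9 ± 22.8 and 80.7 ± 54.2. Among metabolic enzymes, Aldoa was at 153 ± 7.33 and 208 ± 78.4, Ldha at 95.9 ± 11.9 and 243 ± 132 and Hmgcs1 at 50.6 ± 4.66 and 43.4 ± 9.58, and the ATP synthase subunit Atp5b was at 437 ± 27.3 and 715 ± 273. The list of xenobiotic metabolism, a function of the olfactory mucosa, fell, with a median of -0.67 over 12 genes (adjusted p = 2.16e-05, and adjusted p = 0.469 with an estimated correlation). Within it 0 genes fell over all genes tested and 2 fell adjusted over the list alone, the cytochrome Cyp1a2 from 50.9 ± 13.5 to 12.2 ± 9.74 and the retinal dehydrogenase Aldh1a1 from 124 ± 16.6 to 40.2 ± 31.5, while Cyp2f2 was at 1277 ± 130 and 840 ± 350. Cyp1a2 is also on the sustentacular cell list, which stood lower too (camera adjusted p = 0.00125, and adjusted p = 0.469 with an estimated correlation). Whether the xenobiotic list moved apart from those cells was not tested. The p53 median was 0.27 without injured replicate 2. The test and the median pointed in opposite directions for the hemidesmosome, immediate early, cholesterol, oxidative phosphorylation, Bowman gland and fibroblast lists, and for p53 targets the mean (0.11) and the median did, none of them past the threshold.

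Markers of other cells of the mucosa moved differently by cell type, and whether this reflects the cells sorted or their expression was not tested. Mature olfactory neuron genes fell as a list, with a median of -1.30 over 11 genes (camera adjusted p = 3.14e-10, and adjusted p = 0.643 with an estimated correlation). Over all genes tested 0 members fell, and 5 fell adjusted over the list alone. The list mean was -1.83, -0.24 and -1.73 relative to uninjured libraries in injured replicates 1 to 3, and without injured replicate 2 the median was -1.72 and 10 members fell. Among them Stoml3 fell from 416 ± 129 to 124 ± 38.5 FPKM, the olfactory adenylyl cyclase Adcy3 from 15.6 ± 3.06 to 5.38 ± 2.47 and the channel subunit Cnga4 from 9.53 ± 1.74 to 3.32 ± 0.984. Gng13, a G protein subunit of these neurons, was at 60.8, 139 and 126 in the uninjured and at 20.7, 129 and 14.9 in the injured libraries. The sustentacular cell list fell, with a median of -0.46 over 6 genes (adjusted p = 0.00125, and adjusted p = 0.469 with an estimated correlation), with 0 genes over all genes tested and 2 adjusted over the list alone, Cyp1a2 and Muc2. The sustentacular marker Ermn was at 39.7 ± 2.997 and 35.7 ± 11.3. The respiratory ciliated cell list fell, with a median of -0.41 over 9 genes (adjusted p = 0.0171, and adjusted p = 0.816 with an estimated correlation), and no member passed. The call was lost without uninjured replicate 3 (adjusted p = 0.151) or injured replicate 3 (adjusted p = 0.258). Rsph1 was at 13.4 ± 3.89 and 7.87 ± 2.90 and Tppp3 at 17.1 ± 9.91 and 11.9 ± 3.39.

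**Figure D2:**
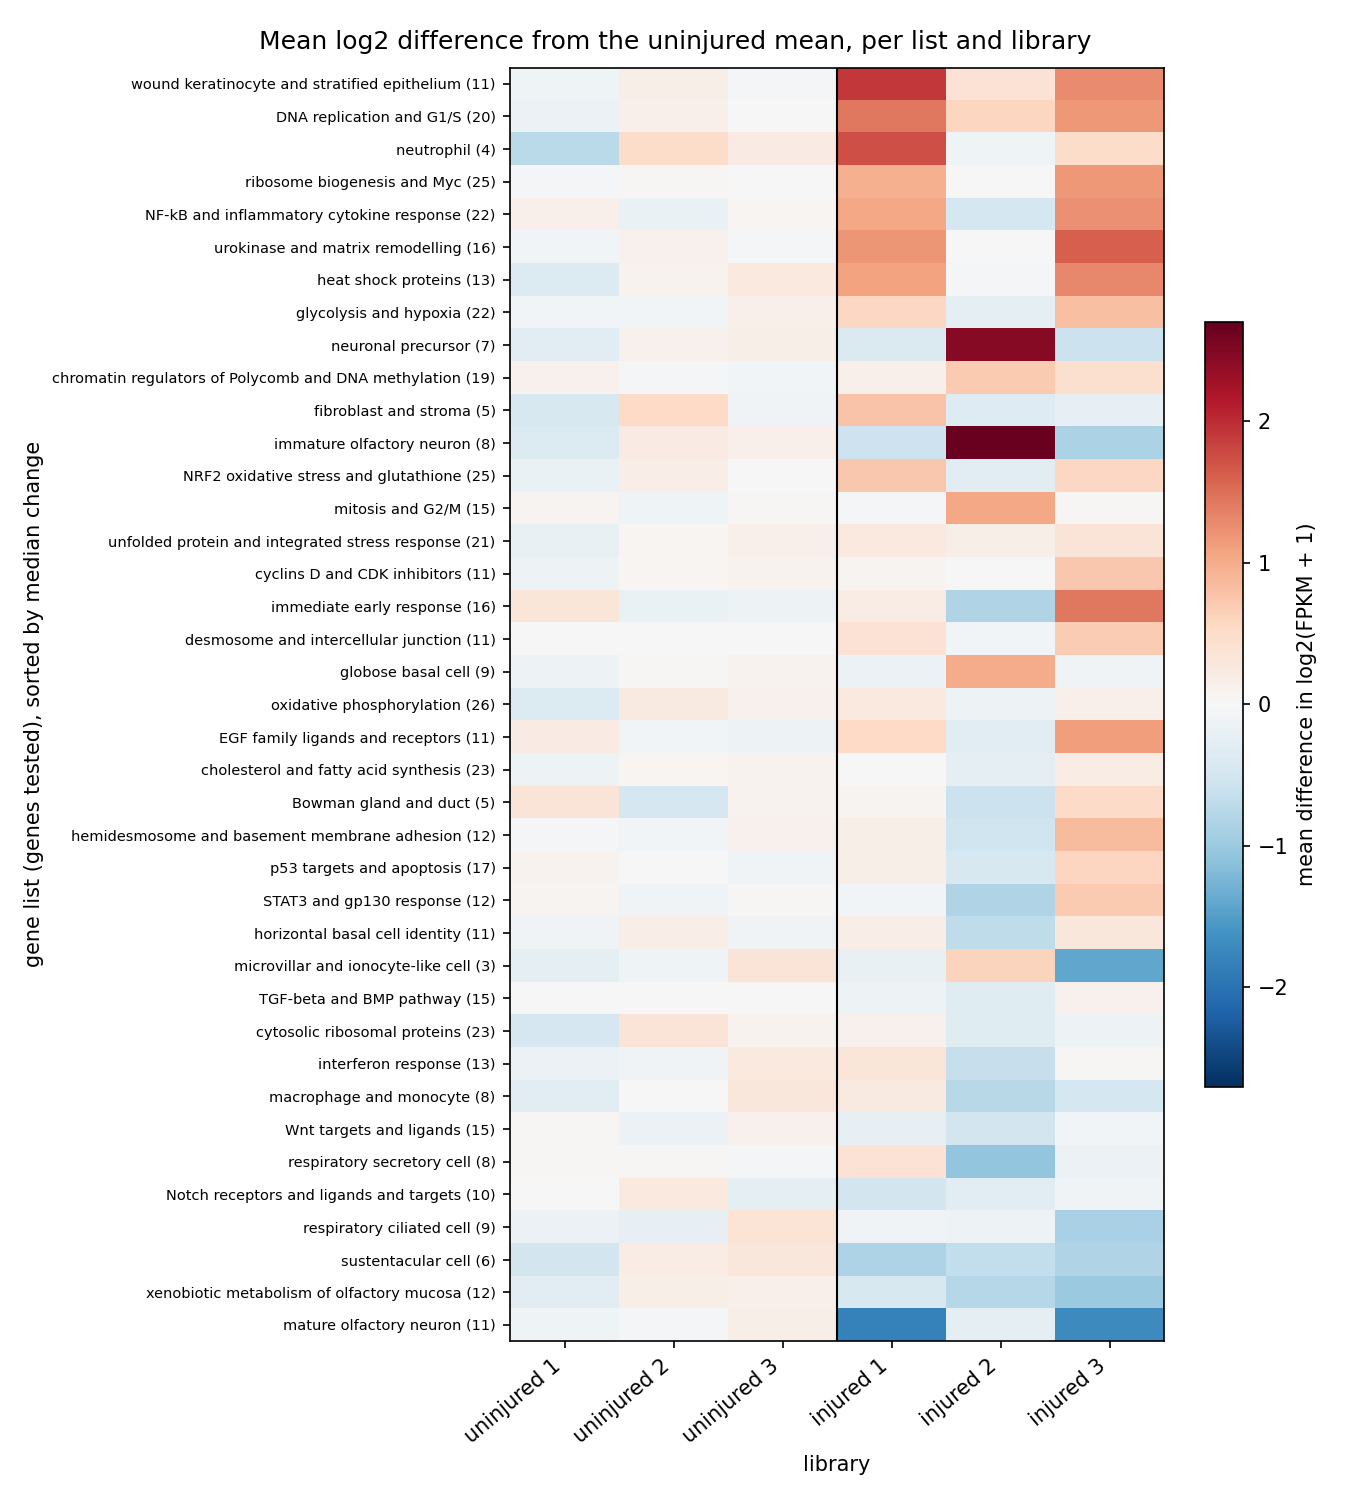
Mean difference in log2(FPKM + 1) from the mean of the uninjured libraries, for each of 39 gene lists (with the number of genes tested) and each library, sorted by the median change. The replication list is at 1.43, 0.58 and 1.16 in injured replicates 1 to 3, and the immature olfactory neuron list at -0.57, 2.67 and -0.86.

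Neuronal lineage genes set injured replicate 2 apart. The lists of globose basal cells, the transit amplifying progenitors (9 genes, median 0.21, camera adjusted p = 0.698, and a median of -0.24 without injured replicate 2), of neuronal precursors (7 genes, median 0.46, adjusted p = 0.463) and of immature olfactory neurons (8 genes, median 0.36, adjusted p = 0.755) did not pass. Yet the immature neuron genes Stmn2 and Stmn1 were at 11.1, 135 and 6.04 and at 37.2, 149 and 26.6 FPKM in injured replicates 1 to 3, against 15.5 ± 3.35 and 38.5 ± 14.5 without injury. The precursor genes Lhx2 and Ebf2 were at 12.2, 112 and 14.1 and at 11.9, 127 and 9.05, against 17.8 ± 4.02 and 18.0 ± 4.70. Ezh2 was at 7.94, 21.0 and 11.6 against 6.83 ± 0.888, while Gadd45g was at 36.2, 13.2 and 24.6 against 24.1 ± 5.76. Without injured replicate 2 the precursor list had a median of -0.70 (adjusted p = 0.0137) and the immature neuron list a median of -0.79 (adjusted p = 0.000884), in the opposite direction to the 6 libraries, with adjusted p = 0.471 and adjusted p = 0.424 when the correlation was estimated.

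The remaining lists of other cell types did not pass. Respiratory secretory products were among the most abundant transcripts, with Plunc at 4082 ± 988 and 1896 ± 620 FPKM and the lectin Reg3g at 1451 ± 238 and 2416 ± 1779 (list median -0.31 over 8 genes, camera adjusted p = 0.169). The macrophage list had a median of -0.23 over 8 genes (adjusted p = 0.0540), with 0 genes over all genes tested and 1 gene that fell adjusted over the list alone, the class II antigen H2-Aa, from 34.1 ± 9.12 to 12.95 ± 4.43, and with Cd74 at 102 ± 52.2 and 45.02 ± 8.42. The fibroblast list had a median of 0.39 over 5 genes (adjusted p = 0.927), with 0 genes over all genes tested and 1 gene that fell adjusted over the list alone, the proteoglycan Dcn, from 141 ± 23.5 to 35.1 ± 24.5 FPKM. Neutrophil genes (4 genes, median 0.76, adjusted p = 0.393) included S100a8 at 14.6 ± 7.13 and 25.2 ± 15.2 and S100a9 at 11.6 ± 5.13 and 23.3 ± 16.5. The Bowman gland list (5 genes, median 0.07, adjusted p = 0.914) held Krt18 at 155 ± 20.04 and 356 ± 222 and Ltf at 42.6 ± 19.3 and 82.6 ± 49.0, and the microvillar list (3 genes, median -0.14, adjusted p = 0.341) held Coch at 84.4 ± 12.3 and 56.7 ± 49.3 and Cftr at 5.13 ± 2.43 and 5.87 ± 3.89. The lists of lymphocytes, ensheathing glia, endothelium and pericytes, erythroid cells and mitochondrially encoded genes had fewer than 3 genes in the table and were not tested.

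**Figure D3:**
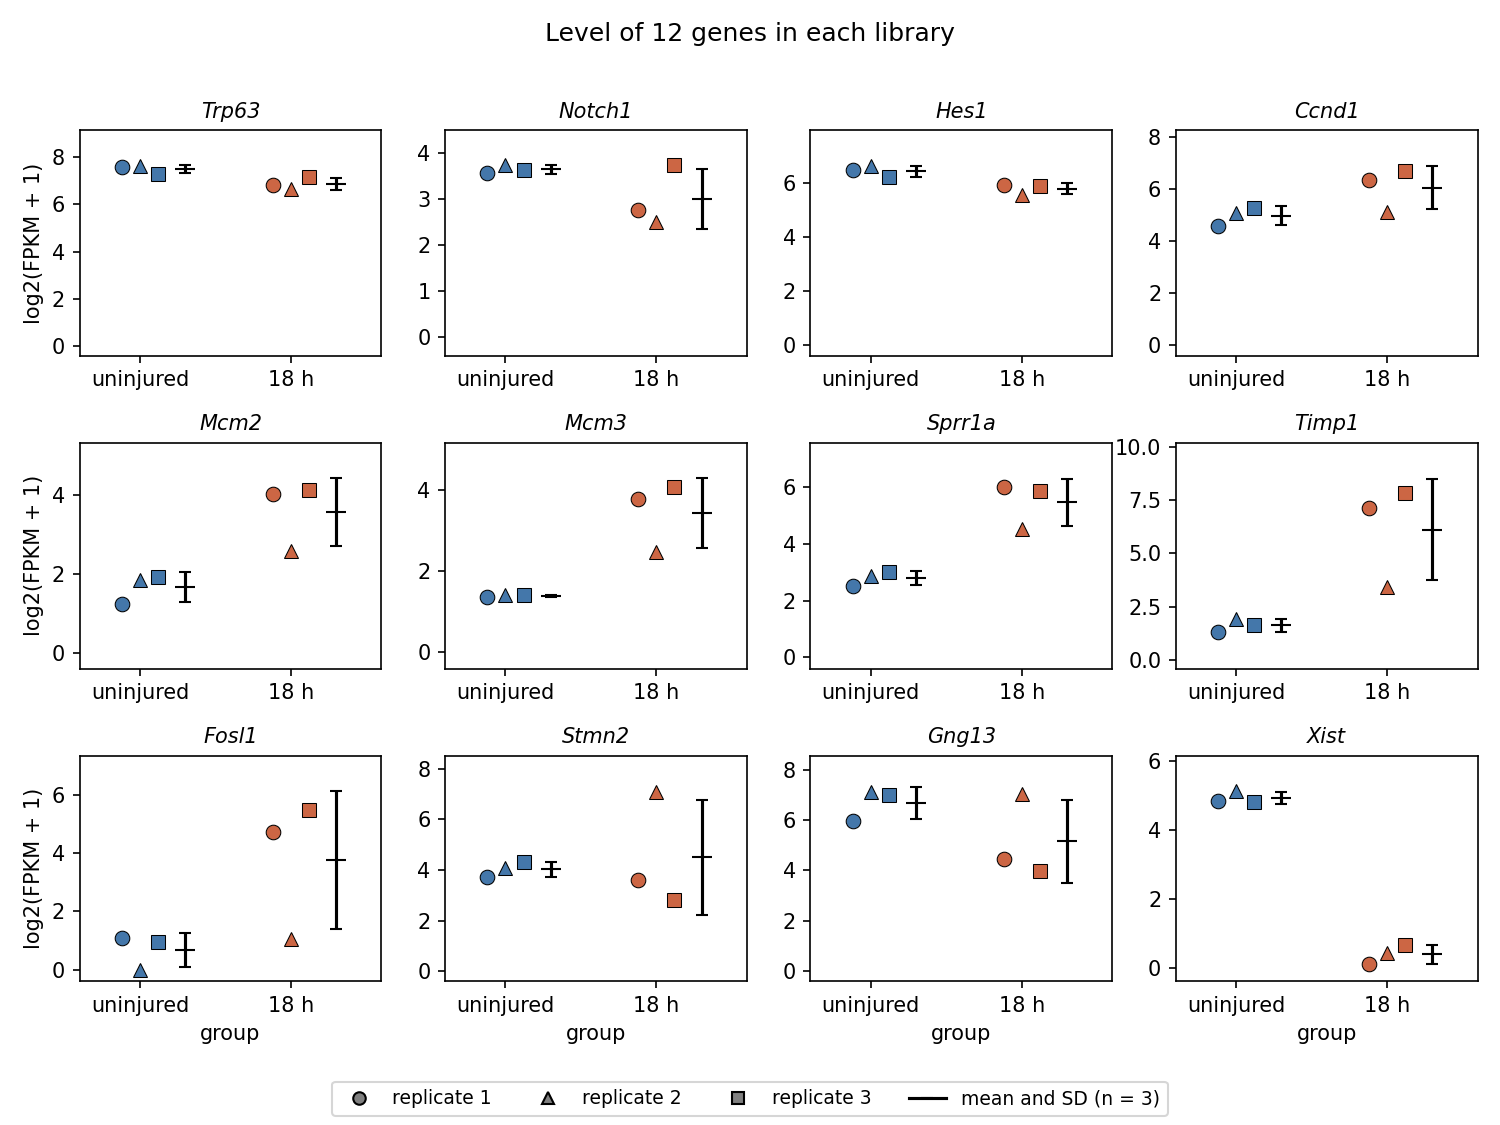
log2(FPKM + 1) of 12 genes in each library, with replicate numbers as symbols and the mean and SD of each group (n = 3) as bars. Xist separates the groups without overlap, at 27.0 to 33.8 FPKM in the uninjured libraries and at 0.0645 to 0.561 in the injured ones, whereas injured replicate 2 lies apart from the other injured libraries for Timp1 and Stmn2.

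Xist had a log2 change of -4.53 ± 0.29 (SE; limma adjusted p = 0.000223) and was at 0.0645, 0.346 and 0.561 FPKM in injured replicates 1 to 3. Genes of the Y chromosome changed in the opposite direction on average, although none passed. Eif2s3y was at 18.8, 2.73 and 2.55 FPKM in the uninjured and at 22.98, 29.3 and 21.1 in the injured libraries, and Ddx3y at 6.67, 1.21 and 1.55 and at 7.74, 8.90 and 11.6. Uty was at 3.71, 0.439 and 1.62 and at 13.7, 9.91 and 7.10, and Kdm5d at 3.33, 0.656 and 0.631 and at 4.60, 4.72 and 2.85. The sex of the pooled animals was not given in the sources used here.

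Without injured replicate 2 the genes past the threshold included several with low values in uninjured cells. The examples here were chosen after their values were seen. The chemokine Ppbp was listed at 0.001, a value that cannot be read as no expression, in the 3 uninjured libraries and was at 99.1, 3.96 and 106 FPKM in injured replicates 1 to 3 (adjusted p = 0.000117 without replicate 2 and 0.306 with it). Timp1 had a log2 change of 5.84 without that library (adjusted p = 0.000921) and of 4.49 with it (adjusted p = 0.333). The interleukin 1 receptor antagonist Il1rn was at 0.431 ± 0.221 without injury and at 43.1, 2.25 and 36.8 with it, and the AP-1 subunit Fosl1 at 0.671 ± 0.588 and at 25.3, 1.08 and 43.9. Also higher were Tpm2 (9.85 ± 3.26 against 176, 32.9 and 158), the membrane linker Msn (6.97 ± 1.10 against 69.0, 18.0 and 95.9) and the actin bundler Fscn1 (1.98 ± 0.245 against 23.7, 5.36 and 31.7). Of the genes that were lower, Cd36 was at 32.2 ± 0.545 and 10.1 ± 0.189, the glucocorticoid target Tsc22d3 at 45.8 ± 7.34 and 12.4 ± 1.99 and Vmo1 at 102 ± 39.5 and 11.2 ± 5.40, each with all 3 injured libraries below the uninjured ones and with limma adjusted p values of 0.0759, 0.0759 and 0.0683 over the 6 libraries.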

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

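Of the alternatives below, library quality weights, leaving out genes at 0.001 and leaving out Mir703 were chosen after the data were seen. No gene was higher and 1 was lower over the 6 libraries. Leaving out 1 library gave 0 to 278 higher and 1 to 92 lower genes and 3 to 8 higher and 5 to 9 lower lists, with 278, 92 and 8 higher lists without injured replicate 2. There the median residual SD of injured libraries was 0.286 over 2 libraries in place of 0.459 over 3. Having fewer libraries lowers such a median by itself, so the drop is not all due to that library. A replicate block gave 134 higher and 87 lower genes and 6 higher lists, although the numbers do not pair the libraries: the deviations from the group means of libraries with the same number had correlations of -0.0892, 0.0677 and -0.0776. Library quality weights (0.259 for injured replicate 2) gave 85 higher and 49 lower genes and 8 higher lists. Without trend and robust steps 3 genes were higher and 3 lower, and upper-quartile scaling gave 3 lower genes, quantile normalization 4, a pseudocount of 0.1 gave 2 and leaving out genes at 0.001 gave 2. A 2-fold minimum, which by construction asks more, left 1 lower list. The medians of the neuronal precursor list (-0.70, adjusted p = 0.0137) and the immature olfactory neuron list (-0.79, adjusted p = 0.000884) reversed without injured replicate 2, and were 1.04 and 0.98 without injured replicate 3; 6 other medians, none past the threshold in either fit, also changed sign without injured replicate 2 (mitosis, globose basal cell, basal cell identity, interferon, STAT3 and p53). Apart from the 2-fold minimum, the cause was not tested. Among named genes 2531 results kept their direction and side of the threshold, 168 passed it in an alternative and 82 moved; among lists 647 were kept, 40 passed, 6 no longer passed and 44 moved. Read depth is unknown, so what it limits cannot be stated.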

Other observations

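The genes in this paragraph were chosen after their values were seen, form no tested group, and did not pass the threshold over the 6 libraries. The lipocalin Lcn3 was at 85.2, 8.36 and 25.2 FPKM in the uninjured libraries and at 0.001, the lowest value of the table, in each injured one, so no fold is given. Lcn11 was at 28.4, 13.8 and 37.1 and, in injured replicate 1, at 7.41, with replicates 2 and 3 at 0.001. The lipid carrier Apoe was at 366 ± 78.2 and 98.1 ± 31.0 FPKM (n = 3 libraries per group), lower in all 3 injured libraries. Psph, an enzyme of serine synthesis, was at 7.81, 9.95 and 9.55 and at 0.001 in each injured library. Cldn1, a tight junction protein, was at 0.532 ± 0.141 FPKM without injury and at 12.1, 1.00 and 11.5 in injured replicates 1 to 3, and the EGF receptor ligand Hbegf at 3.66 ± 0.555 and at 26.4, 3.09 and 55.1. The chaperone Hsph1 was at 23.9 ± 3.43 and at 163, 32.6 and 219, and thioredoxin (Txn1) at 83.1 ± 13.1 and at 285, 118 and 516. Each of these 4 genes passed the threshold without injured replicate 2.

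The tests on Xist, on injured replicate 2 and on splits of 5 libraries were chosen after the result was seen, and the other splits of the 6 libraries were planned. Xist was lower in every injured library, by -4.53 on the log2 scale. That Xist fell with injury in pools of the same sex is argued against by Y-linked genes, whose smallest change was 1.13 (Kdm5d). That the pools differed in the sex of their animals fits, since the 4 Y-linked genes had a median log2 change of 1.76. Their X-linked copies Ddx3x, Eif2s3x, Kdm5c and Kdm6a were at -0.05, -0.16, 0.01 and -0.04, each less than its SE from 0, and were not part of that test. Uninjured replicate 1 goes less well with sex as the full account of Xist. Its Y-linked genes were raised, yet its Xist lay within the range of the other uninjured libraries. As a hypothesis, more males in the injured pools could also set other changes, and this cannot be told apart, because uninjured replicate 1 alone among the uninjured libraries has raised Y-linked genes (Eif2s3y 18.8 FPKM, injured 21.1 to 29.3, but Uty 3.71, injured 7.10 to 13.7, and Xist at 27.4). There the 369 other genes called without injured replicate 2 had a median share of -0.0243 of their change (quartiles -0.167 and 0.108). That share cannot decide, because these genes were called with uninjured replicate 1 in the uninjured group, which favours a share near 0.

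Injured replicate 2 lay apart from the other injured libraries. As a hypothesis, its pool could have held more globose basal and neuronal lineage cells, although the sort took only cells with the keratin 5 lineage label, and whether such cells carried it was not tested: 22 of 24 members of these lists, or 91.7%, were highest in it, which fits. A dilution of the same response cannot be told apart: the 278 genes higher without this library had a median level in it of 35.2% of the mean of injured replicates 1 and 3 (quartiles 24.8% and 46.2%), against 47.2% for 10 horizontal basal cell genes (quartiles 41.6% and 72.6%). The 10 genes had a median level in it of 53.2% of the uninjured mean (quartiles 49.3% and 55.6%). The 278 genes were picked with this library left out, which favours a low level in it. An uninjured library under a wrong label cannot be told apart either: 47.1% of those genes lay above, and 67.4% of the 92 lower genes below, every uninjured library in it, and Xist was at 0.346 FPKM. With genes picked from injured replicates 1 and 3 and a pair of uninjured libraries, 68.5% to 70.5% of the lower and 54.0% to 61.0% of the higher genes lay beyond that pair in injured replicate 2, against 38.0%, 39.5% and 75.5% of the lower and 37.5%, 39.0% and 59.5% of the higher genes in the uninjured library left out, so most left-out libraries lay under it but the highest did not. The 75.5% belonged to uninjured replicate 1 and the 59.5% to uninjured replicate 3. No single left-out library was as high as injured replicate 2 for both the lower and the higher genes.

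Of the 10 splits of the 6 libraries, 5 called as many genes as the real one, which called 1, with 5 as the highest other. For lists, 9 of 10 splits called at least as many as the real 9, with 22 as the highest other. Of 10 splits of the 5 libraries without injured replicate 2, only the real one (1 split) called as many, 370 genes against 6 as the highest other. Injured replicate 2 was picked out for this after it was seen to lie apart from the other injured libraries. That choice favours the real split, so the 370 genes cannot serve as support for an effect of injury. No splits with another library left out were made. In each case 10 splits are too few for a share under 0.05.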
